A study of Mus musculus with 32 samples.

How the data were processed

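The samples were 16 droplet libraries of mouse spleen cells, named p4001 to p4016, in which RNA, 192 surface antibodies and 18 hashtag antibodies were read from the same cells by a 5′ single-cell chemistry with unique molecular identifiers (UMIs). Per the labels, the mice lacked p40 and were sampled 4 days after a plasmid had been given by hydrodynamic injection, a rapid tail vein injection that brings DNA into liver cells, and each library was a mix of control and test plasmids. A deposited feature reference gave the plasmid and the sex of mouse behind each hashtag. By that reference each library held p40+linker from a male and a female hashtag. Libraries p4001 to p4003 also held p40-p35, p4004 to p4006 p40-CD5L, p4007 to p4009 p40-Clusterin, p4010 to p4012 p40-Pentraxin III and p4013 to p4015 p40-Resistin like gamma, each from a male and a female hashtag, and p4016 held all 12. The reference did not say which plasmid was the control. The plasmid p40+linker was used as comparator because every library held it. The number of mice per hashtag was not given in the sources used here, so p-values measure the spread between hashtag sums, which may be technical.

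The deposited matrices held whole-number UMI counts for 32285 genes, 192 antibodies and 18 hashtags per cell barcode, not normalized, per the file headers. Cell Ranger 7.1.0, Seurat and the mm10 build are named per the submitters' processing notes without a role. The filter that selected the deposited barcodes was not given in the sources used here. Gene positions were taken from the GENCODE vM21 annotation of GRCm38, the assembly that mm10 names.

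Everything that follows was computed here from those counts. Barcodes with at least 500 UMIs, at least 200 genes and at most 10% mitochondrial UMIs were kept, which left 196486 of 198682. A hashtag was called positive in a cell above the lowest point between the 2 modes of its log2 counts in that library. Of the kept barcodes 179136 had 1 hashtag, 3903 none and 13447 several, and the last were left out as doublets of 2 sources. Scrublet marked 3124 of the kept barcodes or 1.59%, from 0 in p4016 up, and at most 20.1% of a library's several-hashtag droplets. After the marked cells with 1 hashtag were left out, 177825 cells were analysed. Doublets within 1 hashtag cannot be seen this way. From the several-hashtag droplets their share was estimated at a median of 4.82% in test hashtags and 0.621% in p40+linker hashtags, since a test hashtag held a median of 44.8% and a p40+linker hashtag 5.49% of a library's cells. Hashtags that a library did not use took 0.0453% of hashtag UMIs.

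Clustering used 3000 cells per library, 2000 variable genes without the members of the fixed gene lists, 40 principal components, 20 neighbours and Leiden clustering at resolution 1.5 (scanpy 1.11.5, leidenalg 0.10.2). The other cells took the cluster most common among 15 neighbours. Clusters were named from marker lists for 20 classes fixed before the data were examined. The scoring rule was set after the scores had been seen. It took a mean log2 excess of at least 1 over the other clusters with a prior of 10 CPM, a lead of at least 1 over the next class and at least 3 markers detected in 10% of cells. Clusters that failed it stayed unnamed, and they held 5.453% (p40-Pentraxin III male) to 10.79% (p40-p35 female) of a source's cells. No cluster was named for gamma-delta T cells, type 1 conventional dendritic cells, platelets, progenitors, stroma or hepatocytes. CPM means counts scaled by the summed UMIs, as edgeR's cpm gives them.

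A source is 1 plasmid and 1 sex, and 12 sources were present. A set is 3 libraries with the same hashtags. Hashtag shares differed within no set beyond sampling error (chi-square p of 0.0728 to 0.814 over 5 sets), so the 3 libraries of a set were taken as lanes of 1 pool, summed, and counted once. The plan fixed before the data were examined had taken each hashtag of each library as a sample with library as a covariate, and that fit was kept as an alternative. A first fit on 12 source sums with no term for set was run, and its calls were seen. Some genes, among them Gm10076 and mt-Atp8, moved with the set in every class there. The fit was then changed to 20 sums, 4 sources in each of 5 sets, with set and plasmid as terms and 10 residual degrees of freedom (19 sums and 9 for NK-like cells). The p40+linker sources recur in each set as if independent, so p may be too small. For the scarcer monocyte-like cells 12 source sums with plasmid alone were used, with 6 residual degrees of freedom. The cells of p4016, the shallowest library per cell, were in the monocyte-like sums and the class contrasts, and in the other 7 classes of the plasmid contrasts only as an alternative.

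Gene contrasts used edgeR 4.0.16 quasi-likelihood tests with TMM factors, filterByExpr and Benjamini-Hochberg adjustment at 0.05 in each class and plasmid. All plasmids shared a fit and therefore an estimate of spread. Antibody counts were tested the same way without a low-count filter, and this plasmid contrast of proteins was added after the hashtag map had been read. Of the 192 antibodies 19 had no count and 115 were under 100 CPM of antibody counts. Antibody changes are relative to the other antibodies, because TMM was computed over antibodies. Class contrasts compared NK-like with alpha-beta T-like cells (CD4 and CD8 together), CD8 with CD4 T-like cells, and monocyte-like with B-like cells, over 24 sums with the 12 sources as blocks and 11 residual degrees of freedom. The plan had written the 16 libraries as blocks, which was kept as an alternative. Both classes of a pair came from the same cells of the same source, which is where the pairing comes from. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation. DESeq2 1.42.0 was the alternative tool. Python 3.11.15 and R 4.3.3 were used.

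The 13 gene lists with 170 members were fixed before the data were examined. They were interferon-gamma-induced genes, type I interferon-induced genes, type 1 effector genes, type 17 genes, the IL-12 family and its receptors, cell cycle, MHC class I presentation, MHC class II presentation, exhaustion and checkpoint, early response to handling, chemokines, haemoglobin and neutrophil granule genes. Genes are named by a rule fixed at the same time. For each contrast it takes up to 3 members per list with the largest change past the threshold, then the 5 highest and 5 lowest changes past it among genes of at least 20 CPM in the higher group. Cell type markers and immunoglobulin, T cell receptor, ribosomal and mitochondrial genes are left out of the second part. Il12b, Il12a, Il23a, Ebi3, Il27, Il12rb1, Il12rb2, Il23r and Ifng are always given where they were measured. For proteins the names come from the 5 highest and 5 lowest past the threshold. Genes outside the rule are said to be so. Some items that the rule takes are counted but not reported here by name. In class contrasts, genes that the clustering had used are not given as results, since they helped to draw the classes.

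Shares of cells were tested with exact permutation tests between sources, two-sided. With 2 sources against 2 the smallest p is 0.333, so a plasmid's 2 sources were also set against the other 10, which was chosen after the data were seen. Correlations of RNA with protein used 100000 permutations. Poisson and binomial intervals are exact 95% intervals and cover counting error only. Where a comparator had no count, folds were computed against 3 counts over the group as a floor. Where it had 1 to 3 counts, the ratio of CPM is given with its exact interval.

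RNA depth ran from 21969033 UMIs in p4010 to 82663039 in p4003, with 26711784 in p4016, and the median per cell from 1432 in p4016 to 3482.5 in p4011. In the set of p40-p35 the p40+linker sums of B-like cells held 7050000 UMIs and those of p40-p35 70200000, so the comparator limits the precision. On simulated counts for that B-like contrast (12910 genes) the fit recovered 30.3% of genes changed 1.5-fold, 73.1% changed 2-fold and 83.1% changed 4-fold. Of its calls 5.38% were false, and 9.23% when each source was simulated to deviate alike in every set. For the NK-like contrast (6348 genes) it recovered 1.59%, 18.2% and 70.3%, with 4.92% false calls and 9.38% in the same worst case. For NK-like against T-like cells (12070 genes) it recovered 65.6%, 84.4% and 98.4%, with 4.32% false calls.

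Alternatives fixed before the data were examined were DESeq2, no low-count filter, no library term or no replicate block, doublets kept, stricter cell filters, thinning to 1000 UMIs per cell, a pseudocount of 10 CPM, size factors from RNA UMIs for proteins, classes from antibody gates, all deposited barcodes for Il12b, an estimated correlation, and each source left out. Those added later were the 12 source sums, each hashtag of each library as a sample, a sex term, p4016 as a sixth set, a stricter hashtag cutoff, cells near several-hashtag droplets left out, limma voom with source as a random block, and class contrasts on 16 libraries or without named sources. The CD3 and Ly-6G antibodies gave no usable cutoff and NK1.1 did not separate cells, so gates were made for B, CD4 T and CD8 T cells and for monocytes only. The CD71 antibody stayed in the protein fits and in the numbers of protein calls, but is not named as a result, because its counts followed a hashtag. Receptor sequences were not analysed here, and no correction for free RNA was made.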

Results

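Gene expression, 192 surface antibodies and 18 hashtag antibodies were measured in single spleen cells of mice that lack p40, 4 days after a plasmid had been given by hydrodynamic injection. The p40 subunit, the product of Il12b, pairs with p35 to form interleukin 12. The plasmids, named by the deposited hashtag reference, were p40+linker, p40-p35, p40-CD5L, p40-Clusterin, p40-Pentraxin III and p40-Resistin like gamma, each given to male and female mice, which makes 12 sources. The 16 libraries fell into 5 sets of 3 that each held p40+linker and 1 other plasmid, and p4016, which held all 12 sources. The libraries held 21969033 (p4010) to 82663039 (p4003) RNA UMIs, and 177825 cells with 1 hashtag were analysed. Levels are UMI counts scaled to CPM, and intervals cover counting error only.

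The targeted gene, Il12b, lies on chromosome 11 from 44400063 to 44414033 on the plus strand of GRCm38. Its transcripts were scarce in every library, from 0.844 CPM in p4014 to 2.37 CPM in p4010. Over all cells 820 Il12b UMIs were counted, 1.31 CPM (1.22 to 1.41). The level was 15.8 CPM (12.8 to 19.3) in mature dendritic cell (DC)-like cells, the class with the highest level. Il12b ran from 1.05 to 1.64 CPM over the 12 sources and did not follow the plasmid. The deleted part of Il12b was not given in the sources used here and UMIs do not show which exons were read, so these counts do not test the label. Il12a, which encodes p35, stood at 22.7 CPM in B-like cells, and Ebi3, a subunit of interleukins 27 and 35, at 114 CPM in neutrophil-like cells. Il12rb2, the signalling chain of the interleukin 12 receptor, stood at 170 CPM and Ifng, which encodes interferon-gamma, at 101 CPM in NK-like cells. Il23a, which encodes p19 of interleukin 23, gave 50 UMIs in all cells, 0.080 CPM.

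The plot of these levels by source shows p40-p35 apart for Ifng and for Il12rb1, the other chain of the interleukin 12 receptor. Over all cells Il12rb1 stood at 13.5 and 15.3 CPM in p40-p35 female and male and between 2.73 and 4.23 CPM in the other 10 sources. Ifng stood at 11.6 and 11.3 CPM in p40-p35 and between 0.758 and 2.73 CPM in the others.

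**Figure D1:**
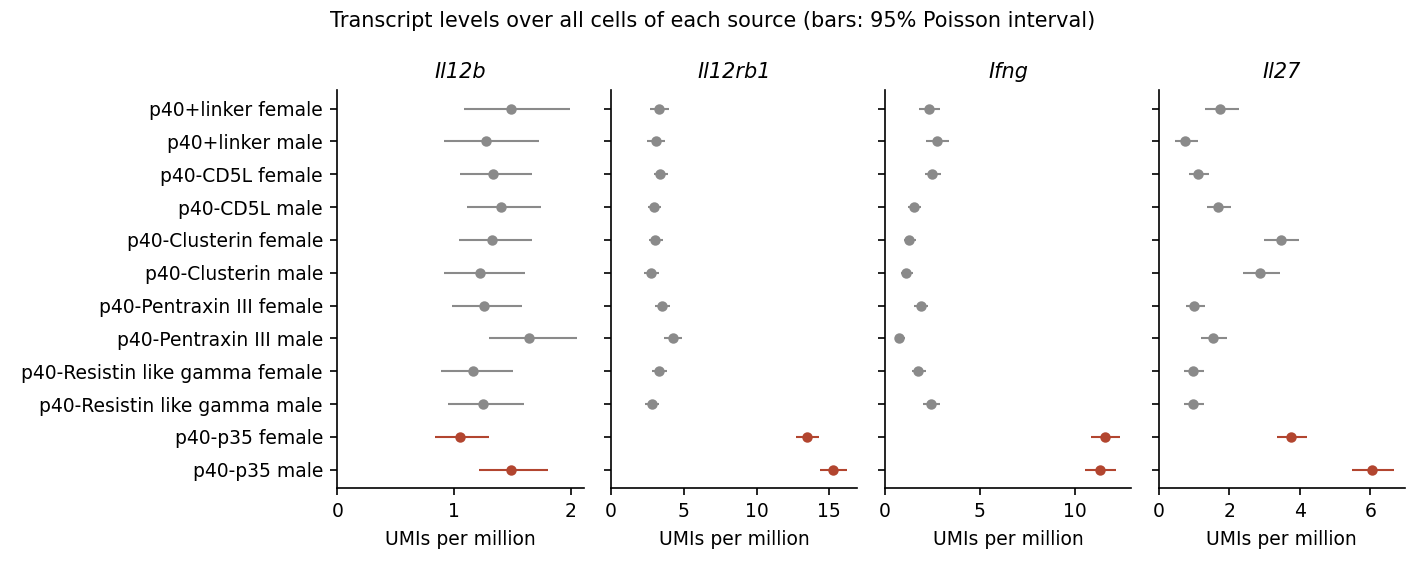
Transcript level over all cells of each source, in CPM, for Il12b, Il12rb1, Ifng and Il27, with 95% Poisson intervals as bars and p40-p35 in red. Il12rb1 is 13.5 and 15.3 CPM in p40-p35, while Il12b runs from 1.05 to 1.64 CPM over the 12 sources.

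The first question was which cell classes the spleens held, library by library. B-like cells made up a median of 57.9% of cells (53.7% to 62.6% over 16 libraries), CD8 T-like cells 12.5% (7.98% to 14.2%), CD4 T-like cells 8.60% (5.24% to 9.86%) and regulatory T-like cells 3.20% (2.14% to 4.05%). Neutrophil-like cells followed with 2.58% (1.41% to 5.10%), macrophage-like cells with 1.79% (0.992% to 3.37%), NK-like cells with 1.22% (0.979% to 1.86%) and monocyte-like cells with 0.987% (0.536% to 2.22%). Mature DC-like cells held 0.684%, plasma-like 0.446%, conventional type 2 DC-like (cDC2-like) 0.361%, plasmacytoid DC-like 0.226%, erythroid-like 0.158% and basophil or mast-like cells 0.0636%.

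The second question was how far the levels of the fixed gene lists differed among libraries. The level is the mean log2(CPM + 1) over a list's members. In B-like cells the interferon-gamma-induced list had a median of 3.65, was at least 5.64 in the 3 libraries with p40-p35, at most 3.83 in p4004 to p4015, and 4.54 in p4016. In monocyte-like cells it was at least 7.09 with p40-p35 and at most 4.17 without, and in macrophage-like cells at least 6.96 and at most 5.10. NK-like cells had a narrower gap, with at least 4.81 and at most 4.10. The type I interferon-induced list was at least 5.74 and at most 4.78 in B-like cells, but in cDC2-like cells it overlapped, with 6.41 as the lowest level with p40-p35 and 6.70 as the highest without. Among single members, Ly6a, which encodes Sca-1, ran from 20.6 to 1844 CPM in monocyte-like cells. These libraries differ in plasmid, so their spread is no replicate error.

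**Figure D2:**
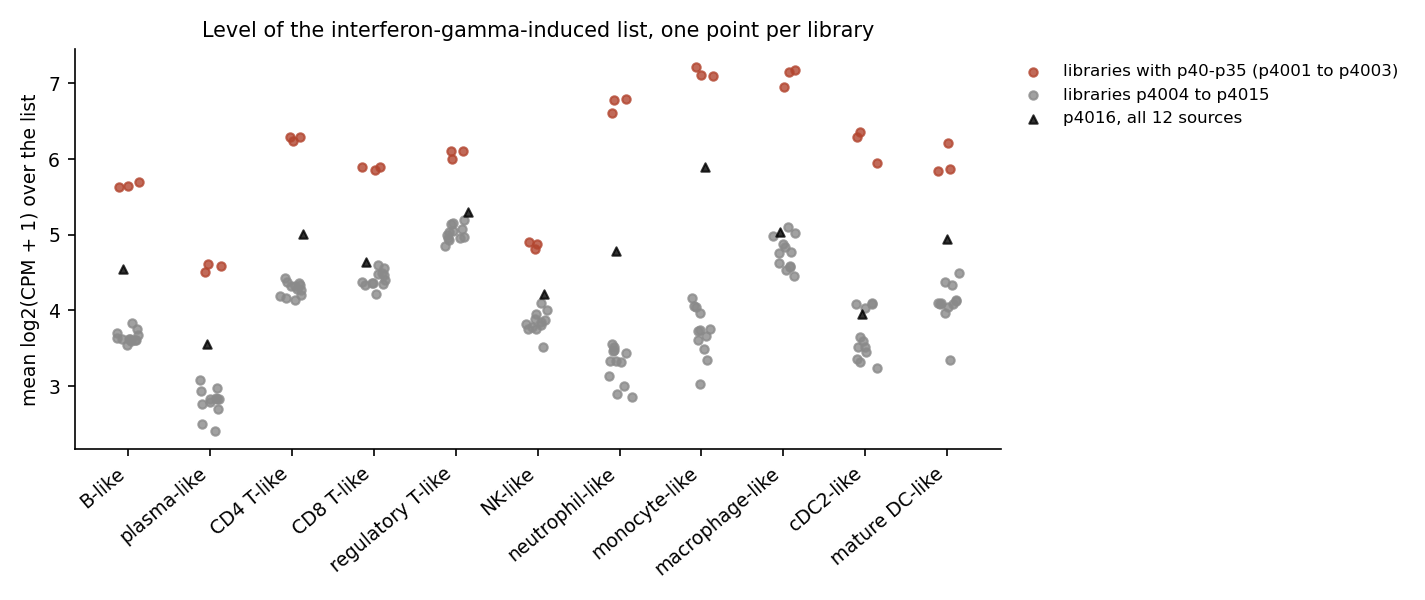
Mean log2(CPM + 1) of the interferon-gamma-induced list in 11 cell classes, 1 point per library, with the 3 libraries that held p40-p35 in red, p4004 to p4015 in grey and p4016 as a triangle. The red points lie above all grey points in each class plotted, in B-like cells at least 5.64 against at most 3.83.

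The main comparison set each plasmid against p40+linker, within its set in 7 cell classes. In the scarcer monocyte-like cells it ran over all libraries, so set effects can enter. The plasmid p40-p35 is named for both subunits of interleukin 12. At least 3 interferon-gamma-induced genes passed as higher with p40-p35 in each of the 8 classes, although the list as a whole missed the threshold in NK-like cells with an estimated correlation. The number of genes past the threshold of edgeR's quasi-likelihood test after Benjamini-Hochberg adjustment ranged from 15 in macrophage-like to 485 in B-like cells. Differences between classes were not tested. All plasmids share the p40+linker sources and thus chance values, so changes alike with several, as of Id3 or Junb, may lie in p40+linker. Comparator sums were small, in macrophage-like cells 67800 UMIs against 1040000 with p40-p35.

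**Figure D3:**
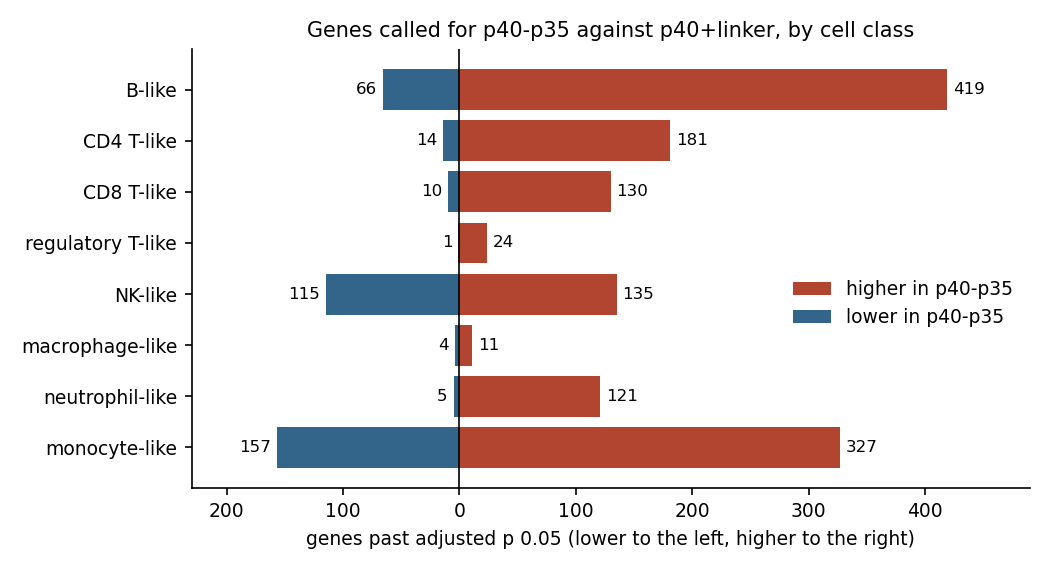
Genes past an adjusted p of 0.05 for p40-p35 against p40+linker in 8 cell classes, with higher genes to the right and lower genes to the left of 0. The bars run from 11 higher and 4 lower genes in macrophage-like cells to 419 higher and 66 lower in B-like cells.

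In B-like cells 419 genes were higher and 66 lower with p40-p35. Of 23 interferon-gamma-induced genes 21 rose (22 when adjusted over the list alone; camera adjusted p = 0.000199 with an estimated correlation). Iigp1, an immunity-related GTPase, rose by 4.74 ± 0.69 on the log2 scale (SE; adjusted p = 0.00263), from 1.39 and 2.86 CPM in female and male p40+linker sums to 46.9 and 66.7 CPM. Gbp10 rose by 5.24 ± 0.67 and Tgtp1, a T cell-specific GTPase, by 4.72 ± 0.66. Cxcl9, a chemokine with no count in p40+linker, was at least 3.52-fold higher. Socs1, an inhibitor of cytokine signalling, rose by 3.78 ± 0.51 and the serpin Serpina3f by 4.65 ± 0.67. The receptor chain Il12rb1 rose by 3.82 ± 0.40 (adjusted p = 7.26e-06), from 0.555 and 1.14 to 10.5 and 13.6 CPM. All 12 MHC class I presentation genes rose (12 when adjusted over the list alone; 0.000199 likewise), among them the transporter Tap1 by 1.29 ± 0.11 (adjusted p = 7.17e-07), the immunoproteasome subunit Psmb9 by 1.40 ± 0.16 and the transactivator Nlrc5 by 2.23 ± 0.24. Of 19 type I interferon-induced genes 10 rose (19 when adjusted over the list alone; 0.0172 likewise), with the nucleic acid sensor Zbp1 at 2.97 ± 0.38.

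Smaller changes in B-like cells included the replication helicase subunit Mcm6, up by 0.67 ± 0.10, and the transcription factor subunit Jun by 0.84 ± 0.19. Atf3, a stress-induced factor, had a count ratio of 9.74 (2.66 to 81.0). Id3, an inhibitor of basic helix-loop-helix factors, fell by 0.70 (adjusted p = 4.04e-05), from 151 and 133 to 86.3 and 88.7 CPM, and Vpreb3, a chaperone of the pre-B receptor, fell by 0.66. No change passed for Ebi3 (-0.59 ± 0.17, adjusted p = 0.0574), Il12a (-0.34 ± 0.37, adjusted p = 0.792) or Il12b (adjusted p = 0.999). Cluster 4 of the B-like cells, led by Serpina3f, Pkib, Serpina3g and Ifit3, held 34.8% and 50.7% of B-like cells in p40-p35 female and male and 3.0% and 3.1% in p40+linker. The count of 485 genes was 303 by limma voom with source as a random block, 48 without p40+linker female, 50 without p40+linker male, 255 without p40-p35 male, and 799 and 806 without p40-Pentraxin III female and male, which enter through the shared spread. Of 22 named genes only Il12rb1 and Tap1 stayed past the threshold whichever source was left out, and 19 lost it without p40+linker female and 19 without p40+linker male.

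In CD4 T-like cells 181 genes were higher and 14 lower. Of 21 interferon-gamma-induced genes 19 rose (21 when adjusted over the list alone; adjusted p = 4.61e-05 with an estimated correlation). Gbp2 rose by 4.09 ± 0.28 (adjusted p = 1.86e-10), from 20.4 and 21.7 to 289 and 429 CPM, Iigp1 by 3.94 ± 0.46 and Gbp10 by 4.34 ± 0.59. Gbp3 had a count ratio of 13.0 (3.56 to 108) and Ube2l6, a conjugating enzyme of the ubiquitin-like ISG15, of 29.6 (5.26 to 1170). Gm4951 had no count in p40+linker and was at least 18.1-fold higher. Of 19 type I interferon-induced genes 8 rose (19 when adjusted over the list alone; 0.00408 likewise), among them Oasl2 by 4.22 ± 0.55 and Oas1a by 3.14 ± 0.53. All 12 MHC class I presentation genes rose (12 when adjusted over the list alone; 0.000269 likewise), with Psmb9 at 1.42 ± 0.17. The kinase gene Sgk1 fell by 1.23 (adjusted p = 0.0012), from 55.1 and 45.3 to 21.2 and 21.4 CPM, and Sytl2 was lower (-1.58). Il12rb1 missed the threshold with a count ratio of 8.60 (1.49 to 345; adjusted p = 0.16). The count of 195 genes was 109 by limma voom, 66 without p40+linker female, 59 without p40+linker male and 124 without p40-p35 male. Gbp2, Tap1 and Psmb10 stayed past the threshold whichever source was left out.

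In CD8 T-like cells 130 genes were higher and 10 lower. Of 21 interferon-gamma-induced genes 17 rose (21 when adjusted over the list alone; adjusted p = 0.000173 with an estimated correlation), among them the GTPase Igtp by 3.22 ± 0.30 (adjusted p = 8.56e-05) and Ly6a by 2.73 ± 0.28, from 93.8 and 110 to 610 and 746 CPM. The count ratio of Gbp10 was 31.2 (10.6 to 152) and that of Il12rb1 10.2 (2.77 to 84.7; adjusted p = 0.00379), while Gm4951 was at least 12.4-fold higher. All 12 MHC class I presentation genes rose (12 when adjusted over the list alone; 0.000173 likewise), with Psmb10 at 1.04 ± 0.11. Of 19 type I interferon-induced genes 3 rose (17 when adjusted over the list alone; 0.00939 likewise), namely Zbp1, the tetherin gene Bst2 (1.85 ± 0.27) and Oas1a. The membrane protein gene Ifitm3 rose by 3.01 ± 0.68, and Mcm6 and Mcm3, subunits of the replication helicase, by 0.86 ± 0.21 and 0.76 ± 0.19. The thioesterase Acot2 and Rfx1 were lower (-1.22 and -0.90). Ifng was no higher (0.05 ± 0.56, adjusted p = 0.996). Cd74, the MHC class II invariant chain, rose by 1.19 ± 0.25 but turned to -1.12 with CD8 T cells gated on surface proteins. Markers of B cells stood at 75.5 CPM in the same cells against 43.2 CPM in p40+linker. The count of 140 genes was 31 by limma voom, 15 without p40+linker female, 13 without p40+linker male, 55 without p40-p35 male, and 229 and 237 without p40-Pentraxin III female and male. Of 22 named genes only Psmb10 stayed past the threshold whichever source was left out.

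In regulatory T-like cells 24 genes were higher and 1, the adhesion molecule Alcam (-1.43 ± 0.32), was lower. Of 21 interferon-gamma-induced genes 9 rose (17 when adjusted over the list alone; adjusted p = 0.00251 with an estimated correlation), with Gbp6 at 2.41 ± 0.34 (adjusted p = 3.98e-05) and Igtp at 1.95 ± 0.27. Of 17 type I interferon-induced genes 3 rose (15 when adjusted over the list alone; 0.0113 likewise), among them Ifi27l2a by 1.07 ± 0.20, from 2020 and 1970 to 3730 and 4630 CPM, and Rtp4 by 1.78 ± 0.35. Of 12 MHC class I presentation genes 1, the proteasome activator Psme1, rose (0.73 ± 0.17; 8 when adjusted over the list alone; 0.0223 likewise). The count ratio of Gbp10 was 12.3 (3.34 to 103), and Gm4951 rose by 2.63 ± 0.63. Il12rb1 (1.66 ± 0.67, adjusted p = 0.643) and Ifng (count ratio 2.48, 0.795 to 12.5, adjusted p = 0.929) did not pass. The count of 25 genes was 3 by limma voom, 2 and 0 without p40+linker female and male, 50 and 2 without p40-p35 female and male, 16 without either p40-CD5L or either p40-Resistin like gamma source, and 15 without p40-Clusterin female. None of the 11 named genes stayed past the threshold whichever source was left out.

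In NK-like cells 135 genes were higher and 115 lower, the only class with nearly as many lower as higher genes. Ly6a rose by 6.64 ± 0.48 (adjusted p = 1.72e-07), from 25.9 and 17.9 to 1750 and 2670 CPM, and the proprotein convertase Furin by 3.90 ± 0.54 (adjusted p = 2.68e-05). Ifitm1 had no count in p40+linker and was at least 26.3-fold higher, with Ifngas1, a long non-coding RNA beside Ifng, at least 4.53-fold, the repressor Zbtb32 at least 4.01-fold and Tmem106a at least 3.93-fold higher. The chemokine gene Ccl5 fell by 3.03 (adjusted p = 0.0005), from 8490 and 10700 to 1490 and 853 CPM, and the tetraspanin Tspan32 by 3.72 (adjusted p = 2.71e-06), from 112 and 71.5 to 9.16 and 3.52 CPM. Heatr9 was lower (-3.83). The count ratio of Il12rb1 was 14.8 (2.64 to 588; adjusted p = 0.00516) and that of Usp18, which removes ISG15 from proteins, 18.8 (3.35 to 743). Ifng itself missed the threshold (1.43 ± 0.43, adjusted p = 0.0778), with 43.1 and 125 CPM in p40+linker and 161 and 294 CPM in p40-p35, and Il12rb2 differed by -0.05 ± 0.28 (adjusted p = 0.963).

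By list, 3 of 19 interferon-gamma-induced genes rose in NK-like cells (5 when adjusted over the list alone; adjusted p = 0.0775 with an estimated correlation), with Gbp2 at 2.45 ± 0.48 and a count ratio of 5.32 (1.80 to 25.9) for Gbp3. Of 12 MHC class I presentation genes 3 rose (5 when adjusted over the list alone; 0.0775 likewise), namely Psmb10 (0.98 ± 0.24), Psme2 (0.83 ± 0.23) and Psmb8 (0.76 ± 0.20). Of 12 type I interferon-induced genes 1 rose (3 when adjusted over the list alone; 0.851 likewise). Of 22 type 1 effector genes 2 were higher and 2 lower (3 and 2 when adjusted over the list alone). Of 6 early response genes Jun rose by 2.43 ± 0.49 and Ier2 was lower (-1.07). Of 7 MHC class II presentation genes 3 rose (4 when adjusted over the list alone; 0.0775 likewise), H2-Ab1 to at least 5.86-fold, H2-Eb1 with a count ratio of 17.9 (3.19 to 708) and Cd74 by 2.93 ± 0.49. In the same NK-like cells markers of B cells stood at 157 CPM with p40-p35 and 8.76 CPM in p40+linker. The count of 250 genes (135 higher and 115 lower) was 267 (86 and 181) by limma voom, 50 and 20 without p40+linker female and male, 140 and 134 without p40-p35 female and male, and 396 and 404 without p40-Pentraxin III female and male. Of 24 named genes Ly6a, Ifitm1 and Tspan32 stayed past the threshold whichever source was left out.

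In macrophage-like cells 11 genes were higher and 4 lower. Iigp1 had no count in p40+linker and was at least 10.4-fold higher, and Ly6a and Gbp2 rose by 2.88 ± 0.58 and 2.83 ± 0.56. The mannose receptor gene Mrc1 fell by 2.09 (adjusted p = 0.00489), from 468 and 403 to 110 and 96.8 CPM, and the cytokine receptor Il31ra by 1.53. Apoc1, an apolipoprotein gene, and Gphn were lower (-3.09 and -1.82). The sodium-calcium exchanger Slc8a1 rose by 3.06 ± 0.55, the count ratio of Lrmda was 11.2 (3.83 to 54.7), and Tifab was at least 3.18-fold higher. Of 19 interferon-gamma-induced genes 4 rose (14 when adjusted over the list alone; adjusted p = 0.015 with an estimated correlation). Of 12 MHC class I presentation genes 1 rose, Psme2 (1.54 ± 0.35; 8 when adjusted over the list alone; 0.015 likewise), and of 12 type I interferon-induced genes 0 (9 when adjusted over the list alone; 0.0365 likewise). The count of 15 genes was 58 by DESeq2, 0 by limma voom (391 at an unadjusted p under 0.05), 8 and 2 without p40-p35 female and male, 3 without p40+linker male, 80 and 90 without p40-Pentraxin III female and male. It was 29 and 25 without the female and male p40-CD5L source, 29 and 28 without those of p40-Clusterin and 26 without either of p40-Resistin like gamma. None of the 11 named genes stayed past the threshold whichever source was left out.

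In neutrophil-like cells 121 genes were higher and 5 lower. The guanylate-binding genes Gbp5 and Gbp4 had no count in p40+linker and were at least 39.3-fold and at least 10.8-fold higher, Tgtp2 at least 14.6-fold and Gm4070 at least 13.5-fold. Isg15, a ubiquitin-like modifier, rose by 3.42 ± 0.51, from 141 and 171 to 1450 and 1850 CPM and Zbp1 by 5.25 ± 0.91. Of 20 interferon-gamma-induced genes 16 rose (19 when adjusted over the list alone; adjusted p = 0.000203 with an estimated correlation). So did 11 of 18 type I interferon-induced genes (17 when adjusted over the list alone; 0.00663 likewise) and all 12 MHC class I presentation genes (12 when adjusted over the list alone; 0.000219 likewise). Tap1 rose by 3.05 ± 0.35 (adjusted p = 1.83e-05), and the count ratios of Nlrc5 and Psmb10 were 41.5 (7.41 to 1640) and 46.6 (8.32 to 1840). The early response factor Egr1 fell by 2.08, from 117 and 180 to 34.5 and 33.3 CPM and the cystine transporter Slc7a11 by 1.83. Markers of B cells stood at 336 CPM here with p40-p35 and 18.7 CPM in p40+linker, beside 5 MHC class II presentation genes of which 0 passed over all genes (5 when adjusted over the list alone; 0.0291 likewise). By the same edgeR test 562 neutrophil-like genes had an unadjusted p under 0.05, and DESeq2 called 163. The count of 126 genes was 69 by limma voom, 35 and 57 without p40+linker female and male and 65 without p40-p35 male. Gbp4, Nlrc5, Tap1 and Gm4070 stayed past the threshold whichever source was left out.

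In monocyte-like cells 327 genes were higher and 157 lower. Iigp1, with no count in p40+linker, was at least 254-fold higher, Gbp2b at least 32.3-fold, Serpina3f at least 25.8-fold, the nuclease Dnase1l3 at least 24.2-fold, Tgtp1 at least 12.3-fold and Il12rb1 at least 7.78-fold. Il27, the p28 subunit of interleukin 27, rose by 3.43 ± 0.49 (adjusted p = 0.000509), from 5.01 and 2.61 to 43.9 and 50.7 CPM, while its partner Ebi3 differed by -0.31 ± 0.37 (adjusted p = 0.738). The fractalkine receptor Cx3cr1, a marker of patrolling monocytes, fell by 4.16 (adjusted p = 0.0481), from 218 and 243 to 15.9 and 10.0 CPM, and the chemokine gene Ccl9 by 1.49 (adjusted p = 4.22e-05). The chemokine Ccl2 had a count ratio of 20.2 (6.86 to 98.6). Apoc1 fell by 4.03, and Cbr3, Acta2 and the aryl hydrocarbon receptor Ahr were lower (-2.84, -2.30 and -0.96). Of 23 interferon-gamma-induced genes 20 rose (22 when adjusted over the list alone; adjusted p = 0.00696 with an estimated correlation), with a count ratio of 133 (36.7 to 1100) for Gbp4. All 12 MHC class I presentation genes rose (12 when adjusted over the list alone; 0.0228 likewise), with Tap1 at 1.98 ± 0.21.

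Of 9 MHC class II presentation genes 7 rose in monocyte-like cells (9 when adjusted over the list alone; adjusted p = 0.0542 with an estimated correlation), with H2-Aa at 2.57 ± 0.53, from 142 and 421 to 1660 and 1500 CPM, H2-Oa at 2.68 ± 0.62 and a count ratio of 26.9 (4.76 to 1070) for H2-Ob. Among type I interferon-induced genes 2 of 19 rose, Zbp1 (1.95 ± 0.20) and Bst2 (1.01 ± 0.22; 3 when adjusted over the list alone; 0.352 likewise). Of 5 IL-12 family genes 2 rose, Il12rb1 and Il27 (2 when adjusted over the list alone; 0.441 likewise). Cluster 33, led by Lyz2, Klra2, Plcb1 and Gpr141, held 92.1% and 95.7% of monocyte-like cells in p40-p35 female and male and 0 in p40+linker, so these values set different clusters of 1 class side by side. The count of 484 genes was 91 and 191 without p40+linker female and male, 272 and 181 without p40-p35 female and male, and 914 without either p40-Pentraxin III source. Of 25 named genes Zbp1, Tap1, Psmb9, Tap2, Ccl9, Serpina3f and Apoc1 stayed past the threshold whichever source was left out.

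Among the remaining lists with p40-p35, MHC class II presentation rose by 1 of 7 genes in CD4 T-like cells, H2-DMa (1.08 ± 0.24; 4 when adjusted over the list alone; adjusted p = 0.0609 with an estimated correlation), and by 1 of 7 in CD8 T-like cells (2 when adjusted over the list alone; 0.0638 likewise). In regulatory T-like cells 0 of its 7 genes passed (2 when adjusted over the list alone; 0.0366 likewise) and markers of B cells stood at 128 against 53.6 CPM, with 40.9 against 19.3 CPM in CD4 T-like cells. In B-like cells, which use these genes themselves, 0 of 9 passed (1 when adjusted over the list alone; 0.93 likewise). Of 14 cell cycle genes 1 rose in B-like cells (2 when adjusted over the list alone; 0.282 likewise) and 2 in CD8 T-like cells (4 when adjusted over the list alone; 0.173 likewise). Early response genes in CD4 T-like cells gave 0 of 6 calls (2 lower when adjusted over the list alone; 0.0319 likewise).

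On the cell surface, p40-p35 cells carried more PD-L1 (CD274) and Ly-6A/E, the protein of Ly6a. CD274 was higher by 0.71 in B-like cells (adjusted p = 0.00249), from 12900 and 11700 to 21300 and 18900 CPM of antibody counts. It was higher by 0.96 in CD4 T-like, 0.94 in CD8 T-like, 0.56 in regulatory T-like, 0.52 in NK-like, 0.88 in macrophage-like and 2.12 in neutrophil-like cells. It did not pass in monocyte-like cells (1.38, adjusted p = 0.288). Ly-6A/E was higher in all 8 classes, by 1.28 in CD8 T-like, 1.60 in NK-like (adjusted p = 0.027) and 2.44 in monocyte-like cells (adjusted p = 0.00963), the last from 6950 and 6900 to 35300 and 39900 CPM. Macrophage-like cells carried less CD14, a co-receptor for lipopolysaccharide, with 22900 and 23400 against 10800 and 10900 CPM (log2 change -1.09, adjusted p = 4.69e-08), and less CD68 (-0.67). NK-like cells carried less NK1.1 (-0.64, adjusted p = 0.00314) and CD96 (-0.40). Neutrophil-like cells carried more I-A/I-E, the MHC class II protein (1.21), beside more B cell markers. Over the 8 classes 30 antibody changes were higher and 11 lower, 4 of the latter for CD71, whose counts followed a hashtag, and with size factors from RNA UMIs the split was 15 and 147, so that directions are relative to the other antibodies.

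As for shares, CD8 T-like cells made up 8.52% and 8.53% of p40-p35 female and male cells and 10.97% and 10.86% of p40+linker cells. Monocyte-like cells made up 1.78% and 2.23% with p40-p35 and 1.25% and 0.433% with p40+linker. With 2 sources on each side the exact permutation test cannot go below 0.333. Against the other 10 sources, p40-p35 differed by -4.07 percentage points for CD8 T-like cells (exact permutation p = 0.0303), 1.08 for monocyte-like cells (p = 0.0303) and 0.147 for erythroid-like cells (p = 0.0152). NK-like shares differed with p40-Resistin like gamma (exact permutation p = 0.0303). After adjustment over 70 comparisons the lowest of these p was 0.53, and no share passed.

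With p40-CD5L, named for p40 and the macrophage protein CD5L, 13 genes passed over the 8 classes. Junb, an early response transcription factor subunit, was lower in B-like cells (-0.74 ± 0.10, adjusted p = 0.00131), from 167 and 210 to 114 and 112 CPM, in CD4 T-like cells (-0.92 ± 0.15) and in CD8 T-like cells (-0.90 ± 0.14). In B-like cells Id3 (-0.69 ± 0.09) and Gm42722 (-1.31 ± 0.17) were lower too, and the chaperone Hspa8 and the receptor Gpr171 rose by 0.62 ± 0.10 and 0.57 ± 0.10. Jund was lower in CD4 T-like cells (-0.58 ± 0.11), Cd74 rose in CD8 T-like cells by 2.23 ± 0.31, and Slc8a1 rose in macrophage-like cells by 2.70 ± 0.47. In monocyte-like cells Gm10076, a ribosomal pseudogene that also moved with the set in p40+linker cells, was lower (-1.76 ± 0.21). The early response list was lower in CD4 T-like cells with 1 of 6 genes past the threshold (4 when adjusted over the list alone; adjusted p = 0.000955 with an estimated correlation), in CD8 T-like cells with 1 of 6 (4 when adjusted over the list alone; 0.00113 likewise) and in B-like cells with 1 of 9 (2 when adjusted over the list alone; 0.00574 likewise). The MHC class II list was higher in CD8 T-like cells with 1 of 7 (4 when adjusted over the list alone; 0.0064 likewise), where B cell markers stood at 70.2 against 39.6 CPM. In regulatory T-like, NK-like and neutrophil-like cells edgeR called 0 genes, with 449, 425 and 249 at an unadjusted p under 0.05, and DESeq2 called 0, 0 and 0. Limma voom, not run on monocyte-like cells, gave 4 against 11 in the other 7 classes and ended the calls of Hspa8, Gpr171, Cd74, Slc8a1 and, in CD4 and CD8 T-like cells, Junb. The count of 13 was 8 and 3 without p40-CD5L female and male, 5 without p40+linker male and 44 without either p40-Pentraxin III source. No named gene kept the call whichever source was left out.

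With p40-Clusterin 6 genes passed. In B-like cells Junb was lower, from 180 and 190 to 112 and 112 CPM (-0.72 ± 0.10, adjusted p = 0.0042), and so was Id3 (-0.61 ± 0.09). H2-Eb1, an MHC class II chain, rose in CD8 T-like cells by 2.23 ± 0.40 (adjusted p = 0.0298), where B cell markers stood at 69.7 against 36.3 CPM. The MHC class II list there had 1 of 7 genes past the threshold (4 when adjusted over the list alone; adjusted p = 0.00112 with an estimated correlation). In monocyte-like cells the B cell genes Bank1 and Cd79b rose by 2.11 ± 0.33 and 1.94 ± 0.31, the last named after its value was seen. The early response list was lower in B-like cells with 1 of 9 (2 when adjusted over the list alone; 0.0118 likewise) and in CD4 T-like cells with 0 of 6 (1 when adjusted over the list alone; 0.00479 likewise). In CD8 T-like cells the type 1 effector list of 21 genes was lower as a whole with no gene past the threshold (0.028 likewise). EdgeR called 0 genes in CD4 T-like (490 at an unadjusted p under 0.05; DESeq2 1), regulatory T-like (474; 0), NK-like (420; 0), macrophage-like (245; 0) and neutrophil-like cells (235; 0). Limma voom gave 3 against 3 in 7 classes, but ended the call of H2-Eb1. The count of 6 was 3 and 11 without p40-Clusterin female and male, 18 and 19 without p40-Pentraxin III female and male and 0 and 3 without p40+linker female and male. No named gene kept the call whichever source was left out.

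With p40-Resistin like gamma 10 genes passed. In CD4 T-like cells the early response genes Jun (-1.56 ± 0.23, adjusted p = 0.000407), Ppp1r15a (-1.18 ± 0.21) and Junb (-1.04 ± 0.15) were lower, the last from 460 and 457 to 228 and 219 CPM. Junb was also lower in B-like cells (-0.84 ± 0.10, adjusted p = 0.00053) and in CD8 T-like cells (-0.77 ± 0.14, adjusted p = 0.0336). The early response list was lower in CD4 T-like cells with 2 of 6 genes past the threshold (4 when adjusted over the list alone; adjusted p = 4.45e-05 with an estimated correlation), in CD8 T-like cells with 1 of 6 (4 when adjusted over the list alone; 0.00164 likewise), in B-like cells with 1 of 9 (2 when adjusted over the list alone; 0.00834 likewise) and in regulatory T-like cells with 0 (2 when adjusted over the list alone; 0.0138 likewise). The count ratio of H2-Aa in CD8 T-like cells was 12.7 (3.47 to 105), where B cell markers stood at 50.1 against 30 CPM, and 1 of 7 MHC class II genes passed (4 when adjusted over the list alone; 0.00669 likewise). The histone genes Hist1h2bg and Hist1h3f were lower in NK-like cells (-4.04 ± 0.75 and -3.14 ± 0.55), a fit without p40+linker female in that set. Gm10076, which moved with the set, was lower in monocyte-like cells (-1.91 ± 0.23). The immunoglobulin gene Ighv7-3, named outside the rule after its value was seen, rose in B-like cells by 1.48 ± 0.23. EdgeR called 0 genes in regulatory T-like (540 at an unadjusted p under 0.05; DESeq2 1), macrophage-like (277; 2) and neutrophil-like cells (216; 0). Limma voom gave 8 against 9 in 7 classes and ended the calls of Ighv7-3, H2-Aa and, in CD4 and CD8 T-like cells, Junb. The count of 10 was 3 and 4 without p40-Resistin like gamma female and male, 4 without p40+linker female and 22 and 25 without p40-Pentraxin III female and male. No named gene kept the call whichever source was left out.

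With p40-Pentraxin III 36 genes passed, although its male source stood apart from all others. In B-like cells Sesn1, a stress-induced inhibitor of mTORC1, rose by 1.40 ± 0.21 and the translation inhibitor Pdcd4 by 0.82 ± 0.11. Id3 was lower (-0.90 ± 0.09, adjusted p = 1.98e-05), from 163 and 153 to 85.0 and 84.8 CPM, as were Ier5 (-0.59 ± 0.08) and Zfand5 (-0.49 ± 0.08). In CD4 T-like cells Tnfaip3, an inhibitor of NF-kappa-B signalling, rose by 1.74 ± 0.25 (adjusted p = 0.000146), Txnip by 1.55 ± 0.24, the checkpoint receptor Ctla4 by 1.35 ± 0.28 and the ubiquitin ligase Cblb by 0.69 ± 0.13. In regulatory T-like cells Tnfaip3 (1.49 ± 0.25), Dusp1 (1.71 ± 0.31) and Rgs1 (1.07 ± 0.21) rose, and Crtam (-3.08 ± 0.57) and Id3 (-1.68 ± 0.25) were lower. In CD8 T-like cells Fam241a, Emb and Gm10076 rose by 1.02 ± 0.14, 0.58 ± 0.09 and 0.57 ± 0.10, and in macrophage-like cells Samhd1 and Slc8a1 by 2.88 ± 0.55 and 2.64 ± 0.52. The early response list was lower in CD8 T-like cells with 0 of 6 genes past the threshold (3 when adjusted over the list alone; adjusted p = 0.0187 with an estimated correlation). Limma voom ended the calls of Ctla4, Txnip, Dusp1, Fam241a, Gm10076, Samhd1 and Slc8a1, and in macrophage-like cells it called 0 genes higher and 5 lower.

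In p40-Pentraxin III male different clusters held the classes, since cluster 10 held 46.1% of its B-like cells, cluster 25 93.8% of its neutrophil-like cells and cluster 34 41.2% of its macrophage-like cells, against at most 1.4%, 1.3% and 16.2% in the other sources. EdgeR called 0 genes in NK-like (526 at an unadjusted p under 0.05; DESeq2 2), neutrophil-like (323; 1) and monocyte-like cells (768; 6). The p40-Pentraxin III count of 36 was 22 by limma voom, 3723 without its female source and 9 without p40+linker female. No named gene kept the call whichever source was left out. Proteins changed in 23 tests over the 8 classes with p40-Pentraxin III (11 higher and 12 lower, but 4 and 78 with size factors from RNA UMIs), in 8 with p40-CD5L (5 and 3, but 1 and 16), in 10 with p40-Clusterin (4 and 6, but 1 and 1) and in 21 with p40-Resistin like gamma (11 and 10, but 2 and 2). Of the lower calls 4, 3, 3 and 3 in that order were for CD71, all of those with p40-CD5L. I-A/I-E was higher on neutrophil-like cells with p40-Clusterin (0.97), p40-CD5L (0.83) and p40-Pentraxin III (0.49), but B cell markers were higher there too (209 against 15.6, 302 against 50.3 and 158 against 15.2 CPM). Ly-6C was higher on monocyte-like cells with p40-Resistin like gamma (1.34, adjusted p = 0.0212), from 227000 and 256000 to 601000 and 624000 CPM with TMM factors.

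The remaining comparisons set cell classes of the same 12 sources against each other. The first asked how NK-like cells differ from alpha-beta T-like cells, and 3906 genes were higher and 4525 lower. Of 24 type 1 effector genes 21 rose (22 when adjusted over the list alone; adjusted p = 0.00202 with an estimated correlation), led by the granzyme Gzma at 9.49 ± 0.47 (7355 ± 1192 CPM in NK-like against 14.8 ± 19.2 in T-like sums, SD, n = 12; adjusted p = 2.51e-09), the inhibitory receptor Klrg1 at 7.103 ± 0.23 and the chemokine Ccl3 at 6.87 ± 0.24. Ifng was higher by 4.93 ± 0.18 in 12 of 12 sources (70.5 ± 68.9 against 2.16 ± 1.59 CPM; adjusted p = 9.88e-15). Both receptor chains of interleukin 12 were higher, Il12rb2 by 4.38 ± 0.16 (163 ± 24.1 against 7.86 ± 2.37 CPM) and Il12rb1 by 2.44 ± 0.12, and the shared receptor chain Il6st was lower (-4.00 ± 0.24). All 14 cell cycle genes rose (14 when adjusted over the list alone; 0.31 likewise), with Mki67 at 5.88 ± 0.21. Of 19 type I interferon-induced genes 17 were lower (17 when adjusted over the list alone; 0.426 likewise), among them Oas2 (-6.53 ± 0.29) and Ifi27l2a (-5.16 ± 0.13; 27.0 ± 20.8 against 934 ± 542 CPM). Of 21 interferon-gamma-induced genes 15 were lower and 1 higher (15 and 1 when adjusted over the list alone; 0.59 likewise), among them Iigp1 (-4.40 ± 0.16; lower in 12 of 12 sources), Tgtp1 (-3.95 ± 0.18) and Ly6a (-2.24 ± 0.60; 350 ± 793 against 315 ± 300 CPM), the last higher in 2 of 12 sources, those of p40-p35, and at 0.27 without the block for source.

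Of 6 chemokine genes 4 rose in NK-like cells (4 when adjusted over the list alone; adjusted p = 0.172 with an estimated correlation), among them Ccl4 by 6.05 ± 0.25 and Ccl9 by 3.69 ± 0.49. Checkpoint genes gave 3 higher and 2 lower of 6, with Entpd1 at 4.03 ± 0.15, Tigit at 4.03 ± 0.12 and Lag3 at 2.95 ± 0.22. Type 17 genes gave 4 higher and 1 lower of 6, with Csf2 at 4.21 ± 0.39, Ahr at 2.53 ± 0.24 and the chemokine receptor Ccr6 at 1.53 ± 0.55 (higher in 6 of 12 sources, and 1.26 without p40-Pentraxin III male, where it lost the call). MHC class I genes gave 2 higher and 7 lower of 12, with H2-D1 at 0.47 ± 0.04 and Nlrc5 at -0.78 ± 0.08. MHC class II genes gave 6 higher and 3 lower of 9, with H2-DMb1 at 3.09 ± 0.27. IL-12 family genes gave 2 higher and 2 lower of 6, early response genes 3 and 2 of 9, granule genes 0 and 1 of 3 (S100a9, -0.57 ± 0.21) and haemoglobin genes 0 and 0 of 4. Counts adjusted over the list alone were the same for these. Beyond the lists, Serpinb9b was the highest named gene that had not been used in clustering (10.75 ± 0.21) and Gm14085 the lowest (-9.32 ± 0.25).

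CD8 T-like cells were then compared with CD4 T-like cells, and 3133 genes were higher and 3100 lower. Of 21 type 1 effector genes 18 were higher and 2 lower in CD8 T-like cells (18 and 2 when adjusted over the list alone; adjusted p = 0.00161 with an estimated correlation), led by Ccl5 at 8.21 ± 0.14 (1712 ± 595 against 5.74 ± 2.66 CPM, n = 12) and Xcl1 at 7.31 ± 0.17. Il12rb2 was higher by 2.97 ± 0.16 (10.6 ± 3.45 against 1.32 ± 0.73 CPM). Zbtb7b, the factor that directs the CD4 lineage, was lower (-4.80 ± 0.08), and Gm44174 was higher by 7.35 ± 0.11. Early response genes were lower in 6 of 6 (6 when adjusted over the list alone; adjusted p = 0.0525 with an estimated correlation), with Dusp1 at -1.01 ± 0.12. Of 5 chemokine genes 4 rose (4 when adjusted over the list alone; adjusted p = 0.0608 with an estimated correlation), and of 14 cell cycle genes 12 (12 when adjusted over the list alone; adjusted p = 0.658 with an estimated correlation), with Rrm2 at 1.57 ± 0.22 and Top2a at 1.24 ± 0.13, both short of the threshold in gated classes (0.16 and 0.44). Ly6a was lower in 12 of 12 sources (-0.91 ± 0.07; 223 ± 223 against 398 ± 349 CPM), though not past the threshold without the block for source (-0.84). MHC class I genes gave 7 higher and 2 lower of 12, with Psme1 at 0.46 ± 0.03, and MHC class II genes 5 higher of 8, with H2-Oa at 1.36 ± 0.07.

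Several genes turned their direction when CD8 and CD4 T cells were gated on surface proteins, where the CD4 gate also held 3334 regulatory T-like cells. Ifng was higher in CD8 T-like cells by 5.08 ± 0.40 (adjusted p = 3.83e-16; 3.14 ± 2.46 against 0.060 ± 0.109 CPM) but -0.99 with the gates, and Il12rb1 by 1.57 ± 0.17 but -0.37. The checkpoint genes Tigit (3.93 ± 0.29 but -2.89), Entpd1 (1.87 ± 0.25 but -1.68) and Lag3 (0.96 ± 0.35 but -1.89) did likewise, and Lag3 also lost the call without the 2 p40-p35 sources (0.99, adjusted p = 0.0526). So did Rora (0.83 ± 0.10 but -1.72), Ahr (0.90 ± 0.22 but -1.70), Cxcl10 (1.85 ± 0.27 but -0.66), Gbp3 (1.02 ± 0.14 but -0.16), Tk1 (1.25 ± 0.21 but -0.056) and S100a8 (-0.36 ± 0.11 but 0.74). Of the lists, 3 checkpoint genes were higher and 2 lower of 6, 2 type 17 genes higher and 1, Batf (-0.15 ± 0.05), lower of 3, 2 interferon-gamma-induced genes higher and 3 lower of 21, 2 IL-12 family genes higher and 1 lower of 6, 0 haemoglobin genes of 4, and of 2 granule genes 1 lower. The type I interferon-induced list gave 5 higher and 5 lower of 19 (6 and 6 when adjusted over the list alone), with Ifi44 at -1.15 ± 0.14. For the other lists the counts adjusted over the list alone were the same. Il12b was lower in CD8 T-like cells (-0.88 ± 0.27, adjusted p = 0.00539; 0.863 ± 0.408 against 1.55 ± 0.848 CPM) but not by DESeq2 or with the gates.

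Monocyte-like cells were last compared with B-like cells, and 5004 genes were higher and 6367 lower. All 11 chemokine genes rose (11 when adjusted over the list alone; adjusted p = 0.447 with an estimated correlation), with Ccl9 at 9.81 ± 0.31 (284 ± 86.6 against 0.356 ± 0.560 CPM, n = 12) and Ccl6 at 8.76 ± 0.28. Of 9 MHC class II genes 8 were lower (8 when adjusted over the list alone; 0.578 likewise), with H2-Ob at -5.51 ± 0.32 and H2-Eb1 at -4.01 ± 0.36 (295 ± 319 against 3334 ± 233 CPM). Of 19 type I interferon-induced genes 16 rose (16 when adjusted over the list alone; 0.447 likewise), with Ifi44 at 3.34 ± 0.21. Of 8 IL-12 family genes 4 were higher and 2 lower. Il27 was higher by 4.21 ± 0.59 (adjusted p = 2.77e-05) and Ebi3 by 1.16 ± 0.14, while Il12a (-4.94 ± 0.25; 0.644 ± 0.709 against 24.0 ± 7.82 CPM) and the interleukin 27 receptor chain Il27ra (-4.18 ± 0.17) were lower. Of 5 granule genes 4 rose (4 when adjusted over the list alone; 0.447 likewise), with Mmp8 at 9.498 ± 0.21 and S100a8 at 6.85 ± 0.46.

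Of 23 interferon-gamma-induced genes 10 were higher and 5 lower in monocyte-like cells, with Cxcl9 at 6.38 ± 0.57 (higher in 8 of 12 sources; 39.98 ± 80.9 against 0.401 ± 0.571 CPM). Of 14 cell cycle genes 10 were higher and 1 lower (10 and 1 when adjusted over the list alone; adjusted p = 0.631 with an estimated correlation), with Birc5 at 3.91 ± 0.27 (0.52 with gated classes, short of the threshold) and Mki67 at 3.40 ± 0.40, the last -0.066 with gated classes. Type 1 effector genes gave 10 higher and 5 lower of 20, with Havcr2 at 8.05 ± 0.29. Early response genes gave 7 higher and 3 lower of 10, with Atf3 at 5.18 ± 0.20 and Egr1 at -3.19 ± 0.22 (-0.15 with gated classes, short of the threshold). Type 17 genes gave 3 higher and 1 lower of 5, with Rora at 3.66 ± 0.26, MHC class I genes 5 and 5 of 12, with H2-K1 at -1.09 ± 0.08, checkpoint genes 2 higher of 5 and haemoglobin genes 0 of 4. For these the counts adjusted over the list alone were the same. Beyond the lists, Arhgef37 (12.78 ± 0.15), the lipid receptor Trem2 (12.62 ± 0.15) and Ptpro (11.96 ± 0.13) were the highest.

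Surface proteins followed the classes. NK-like cells carried more CD11b (2.03), CD11c (1.25), CD115 (1.26), NK1.1 (0.95) and CD38 (0.65) than T-like cells and less CD8b (-3.87), CD5 (-3.02), TCR beta (-2.06), CD4 (-2.03) and CD8a (-1.87). CD8 T-like cells carried more CD8b (4.66), CD8a (2.55), Ly-6C (1.40) and CD73 (0.64) and less CD4 (-3.21), folate receptor 4 (-0.87), CD5 (-0.86) and Ly-6A/E (-0.73) than CD4 T-like cells. Monocyte-like cells carried more CD11b (4.62) and Ly-6C (2.99) and less I-A/I-E (-2.46, lower in 11 of 12 sources) and CD38 (-1.43) than B-like cells. The calls were 25 higher and 19 lower, 21 and 11, and 20 and 35 over the 3 comparisons, with CD71 as 1 of the 19 and 1 of the 21. With size factors from RNA UMIs they were 2 and 67, 5 and 81, and 3 and 94, and CD115 (0.52), NK1.1 (0.38) and CD38 (0.04) then lost their calls in NK-like cells.

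Last, transcript and protein of the same gene were correlated over the 10 sources other than p40-p35, which stood apart, in 50 pairs of gene and class. Ly6a and Ly-6A/E in CD8 T-like cells (Pearson's r = 0.910, adjusted permutation p = 0.0133, Spearman's rho = 0.758, adjusted permutation p = 0.183) and Il2ra and CD25, the interleukin 2 receptor alpha chain, in regulatory T-like cells (r = 0.894, adjusted permutation p = 0.0133, rho = 0.806, adjusted permutation p = 0.176) passed by r and none by rho. Without the 2 farthest sources r was 0.651 and 0.813, with adjusted permutation p of 0.409 and 0.332, so neither call held without them.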

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

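The tests of a set effect, of exchanged hashtags, of T cells as most of the class and of doublets at their estimated share, the interaction test of sex, and the limit to pairs with at least 20 cells were chosen after the results had been seen. The free RNA test replaced a void one that had been seen, with its bounds set before its own value was. Results are given here because the male and female sources of a plasmid differed beyond those of the other plasmids by an interaction term (edgeR quasi-likelihood, 12 source sums) or because an antibody that is not read as a result gave counts mainly in 1 source.

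The male and female sources of p40-Pentraxin III, 1 of each and assumed to vary like those of the other plasmids, differed in 1960 genes of B-like, 736 of CD8 T-like, 416 of CD4 T-like, 271 of NK-like, 242 of monocyte-like, 237 of macrophage-like, 165 of neutrophil-like and 67 of regulatory T-like cells. The tables argue against a library or set effect, since in p4016, where this source shared a library with all others, the B-like genes kept 1.026 times their difference (1181 of 1397 with the same sign), although monocyte-like genes kept 0.348 times, from 4 male and 8 female cells. They argue against an exchange of the male and female hashtags, since 0 comparisons of Xist and Ddx3y went against the labelled sex, and against depth, since after thinning the B-like difference was 1.099 times as large. An effect of the plasmid in male mice, a male hashtag of another origin and a single deviating male source stay open and cannot be told apart, because there was 1 male source of that plasmid. Over 8 classes the contrast of p40-Pentraxin III with p40+linker called 36 genes, 3723 without its female source and 50 without its male source.

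For the other plasmids the interaction called few genes, which decides nothing, since the deviating p40-Pentraxin III male source entered their spread. In the order p40-p35, p40-CD5L, p40-Clusterin and p40-Resistin like gamma, calls in CD4 T-like cells were 2, 0, 1 and 0. They were 2, 2, 1 and 4 in regulatory T-like and 4, 2, 0 and 0 in NK-like cells. Macrophage-like cells had 3, 2, 0 and 1, neutrophil-like 1, 1, 3 and 2 and monocyte-like 6, 0, 0 and 0.

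B cell markers were higher in T-like, NK-like and neutrophil-like sums of the 4 plasmids other than p40-p35 than of p40+linker, by a median log2 ratio of 0.883 (0.485 to 1.59) over 12 pairs of class and plasmid. Free RNA stays open although both sides shared their libraries. Haemoglobin genes do not decide it, with log2 ratios of -3.97 to 8.47 over the 12 pairs (median 2.64, and 9.5 UMIs in p40+linker). Doublets within a hashtag, more frequent in larger hashtags, would raise B cell markers and stay open. In p4016, where p40+linker hashtags were smallest, the median was 1.08 (0.161 to 1.66). Over all 20 pairs it fell from 1.59 in the sets to 0.0703, as doublets predict. Without cells near several-hashtag droplets the 12 pairs fell to 0.235. No biological explanation was tested.

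NK-like sums with p40-p35 differed from those with p40+linker in 250 genes (20 without p40+linker male and 50 without p40+linker female). Some T cells in the class stay open, since Cd3e, Cd3d and Trac had log2 ratios of 3.66, 0.935 and -1.35, whose median of 0.935 met neither bound set beforehand. T cells as most of the class are argued against, since these genes stood at a median of 2.69% of their CD8 T-like level. Doublets are argued against for higher genes, since 126 of 135 would need a doublet share over the highest estimate of 7.43% (median need 50.6%). In p4016, with 17 and 13 cells, called genes kept 0.774 times their difference. Leaving out cells near several-hashtag droplets decides nothing, since B cell markers stayed at 113 against 8.94 CPM. A response of NK cells to p40-p35 was not tested.

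The class contrasts were set against 40 exchanges of the classes within random sources, of which 1, the real one, called as many. Proteins, not used in clustering, gave 44, 32 and 55 calls in the NK-like, CD8 T-like and monocyte-like contrasts. The highest others were 25, 10 and 7 (CD71 is 1 of the 44 and 1 of the 32). As class markers encode some of these proteins, chance is not excluded. For genes (8431, 6233 and 11371, highest others 2, 0 and 2) the exchanges decide nothing, since the classes were drawn from the same RNA counts. The plasmid contrasts had 2 sources a side and no such count. The CD71 antibody gave 274.7 CPM of antibody counts in p40+linker male cells (1162 counts) and at most 1.89 in any other source, and its barcode differs from that of hashtag 1 by 3 edits of 15 bases.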

How the results depend on the processing

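DESeq2, the low-count filter, library or block terms, doublets, gates, stricter cell filters for class shares, all barcodes for Il12b, thinning, pseudocount, an estimated correlation for class contrasts, size factors of proteins, the 2 farthest samples and each source left out were planned, and the other alternatives were added after the data had been seen. Unless stated, the cause was not tested. Of 358 alternative values for 48 counts and levels 206 stayed within 1.5 times or the spread. Calls of named genes in plasmid contrasts stayed in 3540 of 4470 values, were lost in 927 and turned in 3, and 631 of the losses came from leaving out a source and 83 of 172 from limma voom. For named genes in class contrasts 959 of 992 stayed, 20 were lost and 13 turned, and for proteins 170 of 180 stayed. The shallow p40+linker sums limit the plasmid contrasts, and several counts rose without a p40-Pentraxin III source, which enters the shared spread.

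Counts of p40-p35 are given for B-like, CD4 T-like, CD8 T-like, regulatory T-like, NK-like, macrophage-like, neutrophil-like and monocyte-like cells (485, 195, 140, 25, 250, 15, 126 and 484), and sums over the 8 classes for the other plasmids (p40-CD5L 13, p40-Clusterin 6, p40-Pentraxin III 36, p40-Resistin like gamma 10). Without the low-count filter, which adds genes to the test, they were 758 in B-like, 277 in CD8 T-like, 55 in regulatory T-like, 387 in NK-like, 103 in macrophage-like, 250 in neutrophil-like and 853 in monocyte-like cells, and 133, 106, 807 and 101 for the other plasmids in that order. Without the library term they were 1177, 492, 405, 121, 1519, 304 and 303 in B-like to neutrophil-like cells and 223, 96, 1127 and 81. With 12 source sums they were 340 in CD4 T-like, 217 in CD8 T-like, 91 in regulatory T-like, 1291 in NK-like, 143 in macrophage-like and 211 in neutrophil-like cells, and 80, 138, 139 and 50. With p4016 as a sixth set they were 941 in B-like, 262 in CD8 T-like, 41 in regulatory T-like, 40 in macrophage-like and 192 in neutrophil-like cells, 45 for p40-CD5L, 11 for p40-Clusterin and 581 for p40-Pentraxin III. Limma voom gave 303 in B-like, 109 in CD4 T-like, 31 in CD8 T-like, 3 in regulatory T-like, 0 in macrophage-like and 69 in neutrophil-like cells, and over these and NK-like cells 4 for p40-CD5L (11) and 22 for p40-Pentraxin III (36).

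With each hashtag of each library as a sample, which counts lanes as replicates, they were 1464 in B-like, 329 in CD4 T-like, 347 in CD8 T-like and 49 in regulatory T-like cells, and over B-like, CD4 and CD8 T-like cells 157 for p40-CD5L (10), 21 for p40-Clusterin (3), 1371 for p40-Pentraxin III (28) and 92 for p40-Resistin like gamma (7). With gated classes they were 183, 128 and 55 for p40-p35, and 0 for p40-CD5L, 1 for p40-Clusterin and 2 for p40-Resistin like gamma. DESeq2 gave 58 in macrophage-like cells and 233 for p40-Pentraxin III, a sex term 36 and 85, and a stricter hashtag cutoff 45 in macrophage-like cells and 20 for p40-CD5L. With 1 source left out the counts of p40-p35 ran from 48 to 806, 59 to 263, 13 to 237, 0 to 50, 20 to 404, 2 to 90, 35 to 171 and 91 to 914 in the order of classes above, those of p40-CD5L from 3 to 44, p40-Clusterin from 0 to 19, p40-Pentraxin III from 9 to 3723 and p40-Resistin like gamma from 3 to 25, where fewer sources enter the fit. NK-like sums without p40+linker male left the set of p40-Resistin like gamma with no comparator, so it was left out there and that plasmid has no such count.

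With size factors from RNA UMIs the protein counts were 162 for p40-p35, 17 for p40-CD5L, 2 for p40-Clusterin, 82 for p40-Pentraxin III and 4 for p40-Resistin like gamma, and 69, 86 and 97 in NK-like against T-like, CD8 against CD4 T-like and monocyte-like against B-like cells. Without the replicate block for source these 3 comparisons called 7521, 4746 and 10035 genes and 42, 22 and 49 proteins, and Ly6a turned to 0.27 in NK-like cells. Of the 13 lists 5, 4 and 5 passed at the preset correlation and 1, 1 and 0 with an estimated one. Gated CD4 and CD8 T cells turned Cxcl10 (-0.66), Gbp3 (-0.16), Ahr (-1.70), Rora (-1.72), Il12rb1 (-0.37), Tk1 (-0.056), Tigit (-2.89), Entpd1 (-1.68), Lag3 (-1.89), S100a8 (0.74) and Ifng (-0.99), where the CD4 gate holds regulatory T cells. Gates turned Mki67 in monocyte-like cells (-0.066) and Cd74 of p40-p35 in CD8 T-like cells (-1.12). Gm10076 of p40-Pentraxin III in CD8 T-like cells turned to -0.32 without the library term and -0.39 with 12 source sums.

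With gates the median share was 18.4% for B and 5.78% for CD8 T cells, since cells outside every gate remain in the total, and with stricter cell filters 0.656% for macrophage-like cells. A pseudocount of 10 CPM moved the median interferon-gamma-induced level in B-like cells to 4.83 and the type 1 effector level in NK-like cells to 7.08, by construction. Of the 2 correlations of RNA and protein 0 passed without the 2 farthest sources and 0 by Spearman's rho. No share passed under any alternative, which the floor of the exact test made likely beforehand. Division by isotype antibodies, gates for NK cells and the classes beyond those gated, and correlations over 16 libraries were not run.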

Other observations

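The genes in which p40-Pentraxin III male cells stood apart are named here after their values were seen, as the interaction term of edgeR gave them with Benjamini-Hochberg adjustment and the spread of the other plasmids' sources. In B-like cells Fkbp5, a co-chaperone that glucocorticoids induce, stood at 159 CPM against 22.0 in the female source of the plasmid and 23.0 and 19.5 in p40+linker female and male (adjusted p = 0.0107). Il7r, the interleukin 7 receptor chain, stood at 58.4 against 2.14 CPM, Pik3ip1, an inhibitor of phosphoinositide 3-kinase, at 135 against 35.7 CPM, Socs3 at 23.3 against 4.46 CPM and Ston1 at 50.5 against 1.29 CPM. Cr2, the complement receptor of follicular and marginal zone B cells, was lower, with 231 against 650 CPM (adjusted p = 1.69e-08). In CD4 T-like cells Fkbp5 stood at 188 against 33.0 CPM and the pro-apoptotic gene Bbc3 at 118 against 15 CPM. The sterol genes Msmo1 (6.17 against 24.7 CPM) and Fdps (14.4 against 48.9 CPM) were lower there. In NK-like cells the cell cycle genes Rrm2 and Ccna2 had no count in the male source, against 133 and 125 CPM in the female one. In neutrophil-like cells the metallothionein Mt1 stood at 167 against 9.56 CPM, and in macrophage-like cells S100a8 at 378 against 27.8 CPM. CD14 protein on neutrophil-like cells stood at 66200 CPM of antibody counts in the male and 8780 in the female source.

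The same male source also differed in its classes, with 8.31% neutrophil-like, 3.802% mature DC-like and 46.9% B-like cells, and 5.79%, 4.63% and 43.1% in p4016. The other sources held 1.43% to 7.02% neutrophil-like and 0.379% to 0.961% mature DC-like cells.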
